A study of Mus musculus with 2 samples.

How the data were processed

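Chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody to the zinc finger transcription factor ZEB1 was done on papain-dissociated cells of the dorsal cortex of ICR mouse embryos at E14.5, per the labels. DNA of 2 biological replicates was mixed before library construction, per the labels' protocols. The run name carries the replicate numbers 3 and 4, per the file headers. The labels give no such numbers, so which replicates were pooled is not known. The series therefore holds 1 ZEB1 ChIP library and 1 input library, and no spread between replicates can be computed. Every p-value below describes this 1 peak list across positions or genes, not a difference between animals.

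Reads were aligned to GRCm38 with Bowtie2 and peaks were called with MACS2, per the submitters' processing notes. The MACS2 version was 2.1.1.20160309, run in paired-end mode on the ChIP library over input at a q cutoff of 0.05 with duplicate fragments kept at most 1 time, per the file headers. Both deposited files list 2343 peaks, and positions, summits, fold enrichments and q values were identical for all 2343. Peak numbers ran from 1 to 2343 with none missing. The deposited fold enrichment is a ratio of the ChIP fragment pileup to the local background that MACS2 estimates from input, at the summit. The deposited signal at each summit is the ChIP fragment pileup, a coverage that was a whole number at all 2343 peaks. The deposited significance is on the −log10 scale, as p-value and q-value. The deposited score equalled 10 times −log10 q cut to a whole number at all 2343 peaks and was not used further. No columns in use were left without a sample (0). The local background of each peak was recomputed from the deposited pileup and ratio, with the 1 fragment that MACS2 adds to both taken off again.

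Gene positions came from a RefSeq gene table of GRCm38.p6, the same build, which gives the start and end of each gene but no strand, transcripts or exons. No genome sequence was at hand. The planned tests of the ZEB1 E-box, of other short sequences and of GC-matched backgrounds were therefore not run, and distances to transcription start sites were replaced by distances to the nearer of both ends of a gene. A gene end can thus be a start or a termination site. A summit was assigned to the protein-coding or listed microRNA gene whose body held it, or otherwise to the gene with the nearest end within 100 kb. This assignment departs from the planned nearest-site assignment and was fixed before any gene result was seen. The table held 21887 protein-coding genes and 7 listed microRNA genes, 21894 in all.

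The share of summits within 1 kb of an end of a protein-coding gene was set against 1000 random placements of the same number of summits per chromosome, between the first and last position reached by a gene or a peak, with a two-sided permutation p whose smallest value is 0.001. Only the 2333 peaks on assembled chromosomes entered. Runs of unknown bases could not be left out of the placements. Gene lists were fixed before the data were examined: 15 lists with 417 distinct genes, 15 of them in more than 1 list. 1 list member was matched through an older symbol. For each list, the number of members with at least 1 assigned peak was set against 10000 random lists of the same size matched on deciles of the length of genome assigned to each gene. The permutation p was one-sided for more members, with Benjamini-Hochberg adjustment over the 15 lists at 0.05. Intervals of shares are exact Clopper-Pearson 95% intervals, and they cover counting error only. Shares of 0 in the text are given as counts without a limit. Tests used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

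Genes were named by a rule written before the data were examined. It takes the genes of the 10 peaks with the highest fold enrichment on assembled chromosomes, the genes of the 10 such peaks within 1 kb of a gene end, and the 5 genes with the most peaks. It also takes up to 4 members per list with the highest fold enrichment, and always Zeb1, Zeb2, Ctbp2, Cdh1, Neurod1 and Pard6b. At gene ends, 6 peaks shared the fold enrichment of the 10th, 9.32, and ties were broken by chromosome and position. Genes named outside the rule are marked as such. Alternatives were a q limit of 1e-05, a fold enrichment of at least 5, a 5 kb window, ends of all annotated genes, and gene bodies with 10 kb on either side. Alternatives chosen after seeing the data left out peaks with a local background above 10 fragments, kept placements within 100 kb of genes, assigned by the nearest end or within 1 kb of an end, drew lists from curated named genes, or matched on 50 length bins.

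Both tests were tested on simulated data. For the placement test, 30% of 2333 random summits were moved to gene ends, and the recovered share was 32.5% where 32.2% was planted or due to chance. With 0% moved, the permutation p was 0.582. For the list test over 21894 genes, a list of 32 genes with unchanged rates had an unadjusted permutation p under 0.05 in 3.5% of 200 simulations. Rates raised 2-fold gave an unadjusted permutation p under 0.05 in 56.5% of simulations, and rates raised 3-fold in 98% of them. The adjustment over lists was not simulated. Adjusted p-values are never below unadjusted ones, so these shares are upper limits for the calls made here. Other list sizes were not simulated. A 2-fold excess in a list of this size is thus often missed.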

Results

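ZEB1 is a zinc finger repressor best known for switching off epithelial genes during epithelial-mesenchymal transition. The series asked where it sits on the genome of embryonic mouse cortex, in connection with neural differentiation, cell migration and the corepressor CTBP2. It compared 1 ZEB1 ChIP library with 1 input DNA library from dissociated E14.5 dorsal cortex, each pooled from 2 biological replicates, so no value below has a replicate error. The ChIP library held 12512918 fragments, of which 10379906 remained after duplicates were removed (17.0% removed). The input library held 11651536 fragments, of which 9508286 remained (18.4% removed). The fragment size was 236 bp, and positions are on GRCm38.

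ZEB1 ChIP gave 2343 peaks over input, most of them short and modest. The median peak was 353 bp wide (quartiles 286 and 463), with a fold enrichment of 5.33 (quartiles 4.55 and 6.12). A fold enrichment of at least 10 was reached by 30 peaks and of at least 20 by 7. The median summit rested on 12 ChIP fragments, for which counting error alone gives an exact Poisson 95% interval of 6.20 to 20.96. At 1297 peaks (55.4%) the local background was at its lowest value of 1.25 fragments (to within 0.001), and at these peaks fold enrichment followed the ChIP pileup alone. A further 82 peaks had a local background above 10 fragments, with a median fold enrichment of 3.28.

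ZEB1 peaks lay mainly at the ends of genes. Of the 2333 summits on assembled chromosomes, 1398 (59.9%, exact 95% interval 57.9 to 61.9) were within 1 kb of an end of a protein-coding gene. Random placements on the same chromosomes put 3.12% there (95% range 2.49 to 3.81), so the observed share was 19.2 times higher (two-sided permutation p = 0.001, the smallest that 1000 placements can give). The ratio was 10.2 for ends of all annotated genes and 5.56 for a 5 kb window. Within 0.25 kb the share was 33.2% against 0.826% by placement. Of the 1398 summits, 1195 fell inside a gene body. Positions inside gene bodies but over 1 kb from an end held 22.5% of summits against 38.6% by placement. Positions outside gene bodies and over 1 kb from an end held 17.6% against 58.3%. In all, 2016 of 21894 genes (9.21%) received at least 1 of 2175 assigned peaks, and 107 received more than 1.

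**Figure D1:**
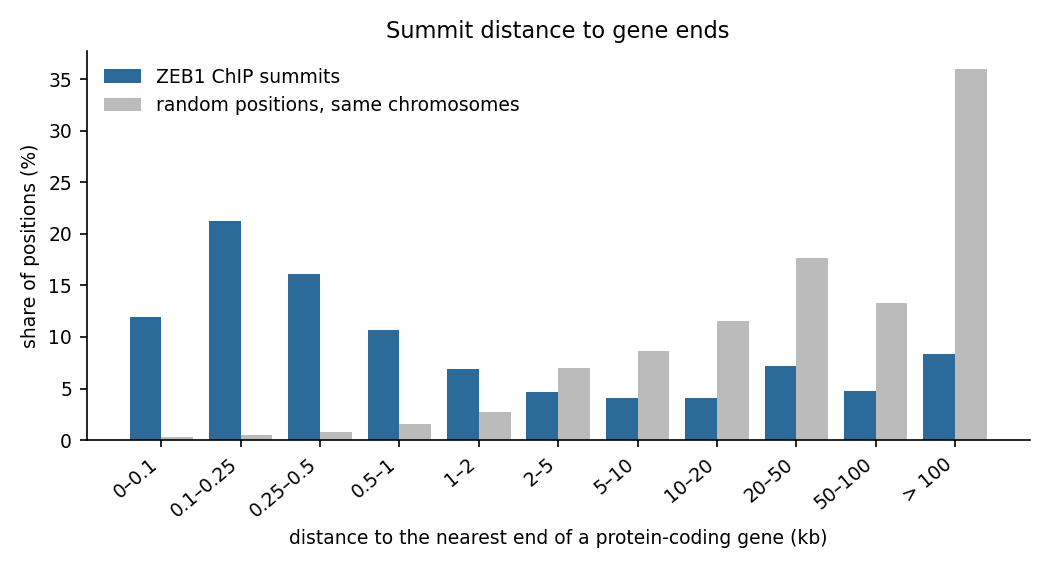
Share of positions (%) by distance to the nearest end of a protein-coding gene (kb, bins of unequal width), for 2333 ZEB1 ChIP summits (blue) and random positions on the same chromosomes (grey). Summits within 1 kb made up 59.9% of the total, against 3.12% by random placement.

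The strongest peaks, in contrast, were away from gene ends. The highest fold enrichment, 110.9 on 249 fragments, was at chromosome 11, 107783182 to 107786371, in the body of Cacng4, which encodes an auxiliary subunit of AMPA-type glutamate receptors. Slc6a17, a synaptic vesicle amino acid transporter gene, held a peak in its body with a fold enrichment of 63.5 at chromosome 3, 107477340 to 107481002. Them7 followed with a fold enrichment of 51.2 and Acvr1b, an activin receptor gene, with 38.3, both in the gene body. The peak assigned to Sec14l1 (fold enrichment 48.4) lay 47.4 kb from the gene. Zswim6 had 23.6 and Nrap 18.6 in their bodies. The peaks assigned to Ifngr1 (22.2) and Dysf (17.8) lay 77.2 and 62.9 kb from these genes. The 10th peak, in the body of Kir3dl2 on the X chromosome, had a fold enrichment of 16.2. Among the 20 peaks of highest fold enrichment, 1 was within 1 kb of a gene end (5%), against 1397 of 2313 others (60.4%, two-sided Fisher exact p = 3.19e-07). This comparison was not planned. Only the top of the range had so low a share, apart from peaks under 3 (0 of 35). The share at gene ends was 57.4% at a fold enrichment of 3 to 5, 64.5% at 5 to 7 and 65.2% at 7 to 10. At 10 and above it was 6.67% (2 of 30).

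Peaks at gene ends reached a fold enrichment of at most 11.98, at Phyhipl on chromosome 10, 70599192 to 70599928. Mtfr1 (10.2), Bcr (9.76), Myo1d and Mblac2 (9.61 each) and Fam241b (9.52) came next by fold enrichment. Nus1, Lemd3, Med11 and Twsg1 stood at 9.32 each. Of these 10 genes, Myo1d encodes an unconventional myosin and Twsg1 a secreted modulator of BMP signalling. Summits at these genes were 22 to 982 bp from the gene's end.

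**Figure D2:**
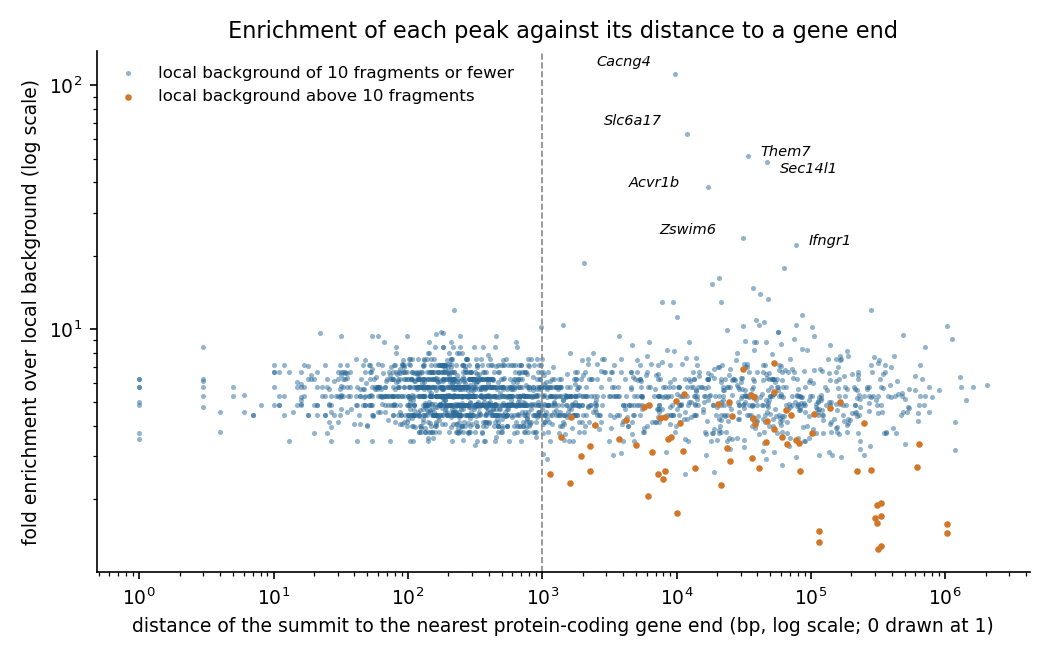
Fold enrichment over local background (log scale) of each of 2333 peaks against the distance of its summit to the nearest protein-coding gene end (bp, log scale), with the 1 kb limit dashed and peaks of local background above 10 fragments in orange. Peaks within 1 kb stayed at or below a fold enrichment of 11.98, while the highest, at Cacng4, reached 110.9.

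The genes with the most assigned peaks were Gm40363 with 11, Gm52481 on the Y chromosome with 8, Hrh1 with 8, Atg7 with 7 and Rhou with 6. Except for 1 summit at 47686079 in Gm40363, all of these summits lay outside the genes and were assigned to the nearest end within 100 kb. Fold enrichment ranged from 2.60 to 6.42 at Gm40363, where 8 of the 11 peaks had a local background above 10 fragments. The summits assigned to Hrh1, a histamine receptor gene, and Atg7, an autophagy gene, lay between these neighbouring genes on chromosome 6, from 114497218 to 114617181. Their fold enrichment ranged from 2.98 to 5.58 for Hrh1 and from 3.28 to 6.95 for Atg7.

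Gene-end summits were spread over all autosomes but were rare on the X chromosome, a comparison chosen after the values were seen. Among named genes with a curated transcript, 1525 of 17669 autosomal genes (8.63%) had a summit within 1 kb of an end, with single autosomes between 6.26% and 11.8%. On the X chromosome 2 of 784 genes did (0.255%), which gave an odds ratio of 0.0271 (95% interval 0.00327 to 0.0983, two-sided Fisher exact p = 5.2e-27). Those genes, outside the naming rule, were Eda, encoding the ligand ectodysplasin, and Map7d2, encoding a microtubule-associated protein, each with a fold enrichment of 4.88. Of the 49 peaks on the X chromosome, the other 47 lay over 1 kb from a protein-coding gene end.

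**Figure D3:**
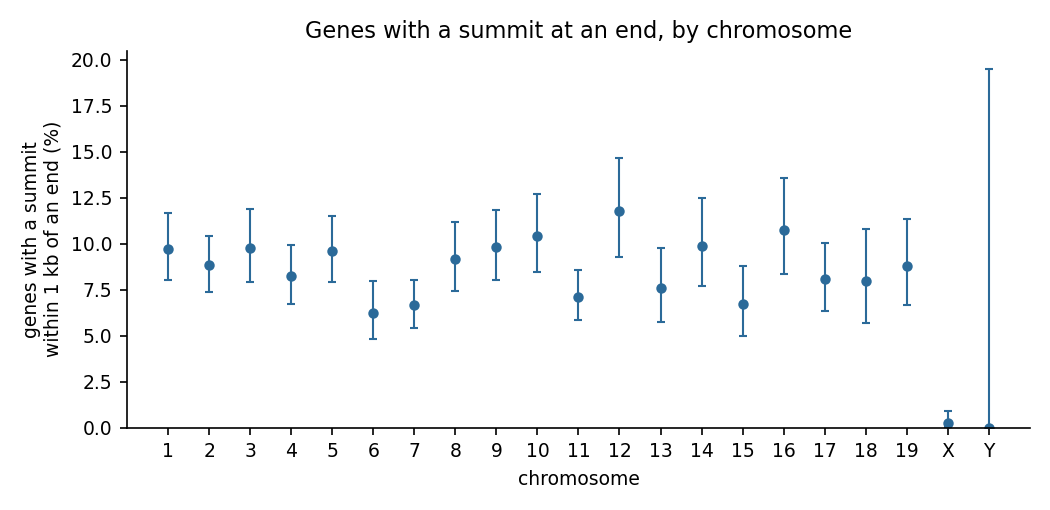
Share (%) of named genes with a curated transcript that had a summit within 1 kb of an end, for each chromosome, with exact 95% intervals. Autosomes lie between 6.26% and 11.8%, and the X chromosome at 0.255%.

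A peak lay at the Zeb1 gene itself. It covered chromosome 18, 5591396 to 5591666, with its summit 142 bp inside the gene's end, a fold enrichment of 4.88 and 10 ChIP fragments. Pard6b, which encodes a component of the apical polarity complex, had a peak at chromosome 2, 168080601 to 168081336, with a fold enrichment of 7.13, 19 fragments and its summit 80 bp outside the gene. No peak was assigned to Zeb2, the paralogue of Zeb1, to the corepressor gene Ctbp2, to the E-cadherin gene Cdh1 or to the neurogenic factor gene Neurod1. The nearest summits were 4334 kb from Zeb2, 361 kb from Cdh1 and 179 kb from Neurod1. The summit nearest to Ctbp2 was 55.7 kb away and was assigned to Zranb1, a gene outside the naming rule. The peak list holds only positions past its threshold, so weaker binding at these genes could not be seen in it.

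Among the 15 gene lists, peaks were over-represented at Wnt pathway genes. Peaks were assigned to 11 of 35 members, against 4.43 in matched random lists, a ratio of 2.48 (one-sided permutation p = 0.0025, adjusted p = 0.0375). The members of highest fold enrichment were the receptor genes Fzd5 (7.10) and Fzd7 (6.12), the kinase gene Gsk3b (6.21) and the beta-catenin gene Ctnnb1 (5.82), all within 1 kb of a gene end. In this assignment the call needed 1 peak of high local background, 61.1 kb from Axin2, a gene outside the naming rule. Without peaks of high local background, 10 members had a peak, at a ratio of 2.29 and an adjusted permutation p of 0.0772, within a range of 0.0225 to 0.764 over all alternatives. The call also ended at a q limit of 1e-05, at a fold enrichment of at least 5 and against curated named genes. With a summit required within 1 kb of an end, which leaves the Axin2 peak out, 8 members gave a ratio of 2.98 and an adjusted permutation p of 0.0322. In that setting random lists came from all genes, and curated named genes were not tried as the background.

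Genes of cell polarity and adherens junctions were next, with 9 of 31 members against 3.86 in random lists, a ratio of 2.33 (permutation p = 0.0122, adjusted p = 0.0915). The members with the highest fold enrichment were Patj (7.54), Pard6b (7.13), Pard3b (6.07) and Ctnnb1 (5.82). The same Ctnnb1 peak also counted for the Wnt pathway list, and the same Patj peak for the epithelial list below. The polarity list did not pass the threshold, but it did when members needed a summit within 1 kb of an end, with a ratio of 3.66 (adjusted permutation p = 0.0075, range over all alternatives 0.0075 to 0.172). That setting, too, was not run against curated named genes.

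Neuronal migration genes and differentiation factors did not pass the adjusted threshold. Peaks were assigned to 10 of 42 neuronal migration genes, against 5.58 in random lists, a ratio of 1.79 (permutation p = 0.0416, adjusted p = 0.196). The ratio for migration genes was 0.970 at a q limit of 1e-05 and 1.19 at a fold enrichment of at least 5. With summits within 1 kb of an end it was 2.43 (adjusted permutation p = 0.0860). The highest fold enrichments were at the netrin receptor gene Unc5d (9.32), at Cdk5r1 (6.66), which encodes the Cdk5 activator p35, and at Dab1 and Tubb3 (5.33 each). Of 32 neuronal differentiation transcription factors, 8 had a peak against 4.25 in random lists, a ratio of 1.88 (permutation p = 0.0523, adjusted p = 0.196). With summits within 1 kb of an end, that ratio was 1.13 (adjusted permutation p = 0.834), and at a q limit of 1e-05 it was 2.53 (adjusted permutation p = 0.328). The 8 factors with a peak included the proneural gene Neurog2 and Neurod6 (6.21 each), Zbtb20 (6.09) and Pou3f2 (6.04). The Neurog2, Zbtb20 and Pou3f2 summits of that height lay 7.22, 96.1 and 53.6 kb from the gene's end.

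The remaining progenitor and signalling lists did not pass the threshold, with ratios to random lists from 1.15 (cell cycle genes) to 1.64 (Notch pathway genes) and adjusted permutation p from 0.526 to 0.742. At a q limit of 1e-05 the ratios were 0.666 for radial glia and progenitor genes, 0.924 for Notch pathway genes and 0 for cell cycle genes, and the interneuron ratio of 1.58 was 0.999 within 5 kb of an end. A 2-fold excess in a list of this size would often have been missed. Peaks were found at 5 of 30 radial glia and progenitor genes, among them Emx2 (6.21), Hmga2 and Nr2f1 (5.33 each) and Pax6 (4.88). Notch pathway genes had 5 of 28, among them Jag2 (5.77), Notch2 (5.69) and Maml1 (4.88). TGF-beta and BMP pathway genes had 6 of 33, led by Tgfbr1 (7.54), Acvr1 (6.97), Bmpr2 (5.77) and Bmp7 (4.88). Corepressors and epithelial-mesenchymal transition factors had 4 of 22, namely Tcf12 (6.21), Kat2b (5.33), Zeb1 (4.88) and Rcor1 (4.44). The ratio for this list was 1.48, and 2.25 with summits within 1 kb of an end (adjusted permutation p = 0.363). Interneuron markers had 4 of 22, among them Lhx8 (5.24), Erbb4 (4.56) and Dlx1 (3.79). Cell cycle genes had 3 of 30, namely Ccne1 and E2f1 (5.77 each) and Ccne2 (4.55). The Acvr1, Tcf12, Lhx8 and Ccne1 summits of the height given lay outside these genes, 20.3, 21.4, 84.8 and 12.9 kb from the gene's end.

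Epithelial genes that ZEB1 represses in other tissues showed no detectable excess of peaks. Peaks were assigned to 2 of 32, Epcam and Patj with a fold enrichment of 7.54 each, against 2.46 in random lists (permutation p = 0.716, adjusted p = 0.976). Their ratio to random lists was 0.813, and it turned to 2.47 at a q limit of 1e-05 and 1.37 at a fold enrichment of at least 5, with the same number of members. Markers of other cell types did not pass the threshold either. Oligodendrocyte and astrocyte markers had 1 of 18 (Mbp, 4.44), microglia and blood cell markers 1 of 23 (Klf1, 4.64), and endothelial, pericyte and meningeal markers 1 of 27 (Foxc1, 6.21). The ratio for oligodendrocyte and astrocyte markers was 0.552, but within 1 kb of an end 2 members had a summit against 1.33 in random lists. Liver and muscle genes had 0 of 26, against 1.95 in random lists, whose central 95% ran from 0 to 5. The test was one-sided for more members, so it could not show a shortage in any list.

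**Figure D4:**
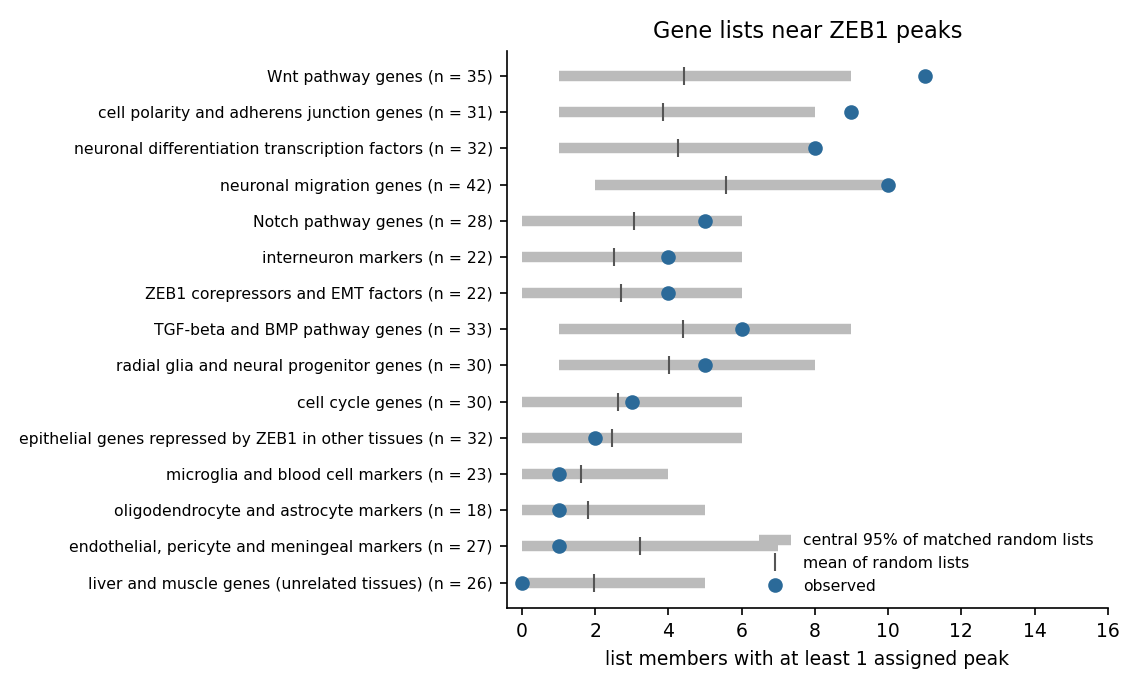
Number of members of each of 15 gene lists with at least 1 assigned peak (blue points), beside the mean (tick) and central 95% (grey bar) of 10000 random lists matched on the length of genome assigned. Wnt pathway genes lie at 11 against a mean of 4.43, and liver and muscle genes at 0 against 1.95, within their grey bar of 0 to 5.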

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

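Peaks left out for high local background, placements near genes, assignment by nearest end or within 1 kb of an end, curated background genes and 50 length bins were alternatives chosen after seeing the data. The number of peaks was 849 at a q limit of 1e-05 and 1336 at a fold enrichment of at least 5. The share at gene ends kept its direction and its permutation p of 0.001 under every alternative run, between 51.8% (q limit of 1e-05) and 71.5% (5 kb window). Its ratio to random placements ranged from 5.56 (5 kb window) to 20.1 (fold enrichment of at least 5), with 10.2 for ends of all annotated genes and 14.0 for placements within 100 kb of genes. The number of lists past the threshold, 1 in the report, was 0 at the q limit, 0 without peaks of high local background and 0 against curated named genes. It was 2 within 5 kb of a gene end, 2 within 1 kb and 2 by nearest end, where Wnt pathway genes and polarity genes both passed. At a fold enrichment of at least 5 it was 1, but that list was the polarity genes. The ratio for Wnt pathway genes was 3.06 at the q limit (5 members, adjusted permutation p = 0.140) and 1.49 at a fold enrichment of at least 5 (4 members, adjusted permutation p = 0.764). It was 2.24 against curated named genes (adjusted permutation p = 0.108), which more often have a peak (10.4% against 9.21% of all genes). Without peaks of high local background it was 2.29, because the Axin2 peak, with 183 fragments and a local background of 50.2, was lost. The cause of the loss at the fold limit was not tested. No E-box, 6-mer, GC-matched, repeat or promoter-GC alternative was run, since these need a genome sequence. No paired analysis was possible because each group has 1 pooled library. The median summit rests on 12 fragments, and how the list depends on depth was not tested.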

Other observations

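Except for the comparison of housekeeping families with other named genes, all tests in this part were chosen after the values were seen. Shares of housekeeping genes with a summit within 1 kb of an end are given by family. Cytosolic ribosomal protein genes (2 of 81, 2.47%), proteasome genes (1 of 40, 2.5%), respiratory complex I genes (1 of 48, 2.08%) and splicing factor genes (0 of 21) had few. Mitochondrial ribosomal protein genes (7 of 78, 8.97%) and ATP synthase and cytochrome oxidase genes (3 of 32, 9.38%) had more, as did genes of translation initiation factors (6 of 56, 10.7%) and RNA polymerase subunits (3 of 28, 10.7%). Chaperonin and coatomer genes had the highest share (3 of 17, 17.6%), and differences among the families were not tested.

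Among 102 gene families of at least 20 members that share the start of a symbol, 1 had summits at its ends more often than other genes. Zbtb genes, which encode BTB-domain zinc finger proteins, had them in 10 of 41 cases (24.4%, against 7.21% of other genes, odds ratio 4.15, adjusted two-sided Fisher exact p = 0.0184). Zbtb14 had the highest fold enrichment of these (6.66), followed by Zbtb48 (6.21), and Zbtb1 and Zbtb25 shared 1 peak, all of them genes outside the naming rule. The shared peak was counted for both genes, so the 10 cases are not independent. Olfactory receptor genes had 0 of 1110 and vomeronasal receptor genes 0 of 355. Both of these families were among the other genes that Zbtb genes were compared with. Among 6 classes of non-coding genes and pseudogenes, 3 had more summits within 1 kb of an end than placements gave (adjusted permutation p = 0.0024 each). Long non-coding RNA genes had 243 summits against 44.9, microRNA genes 16 against 2.01 and tRNA genes 9 against 0.597. Once summits near protein-coding genes were left out, the numbers were 77 against 17.6, 4 against 0.761 and 5 against 0.235, with adjusted permutation p of 0.0024, 0.0240 and 0.0024.

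The concentration of summits at gene ends may reflect ZEB1 binding or signal that open promoters give in any ChIP library. Housekeeping families had a summit at an end in 6.48% of 401 genes against 8.31% of other named genes, an odds ratio of 0.765 whose interval (0.492 to 1.14) holds 1, so this test left open whether open promoters in general contribute. Signal that grows with the size of a CpG island also stays open, since no sequence was used here. No biological explanation was tested, because the design has no sample without ZEB1.

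The 20 peaks of highest fold enrichment lay mostly away from gene ends. Their median width was 1110 bp against 352 bp for the others, and width rose with fold enrichment among all peaks from 3 upwards, from a median of 329 bp at 3 to 5 to 758.5 bp at 10 and above. The local background at these peaks had a median of 1.27 fragments and reached at most 2.73. Ranking by fold enrichment left room for a background above 10 at 3 of the 20. These, at Cacng4, Slc6a17 and Them7, had 1.25, 1.25 and 2.18 fragments, so no background above 10 was seen there. At the others the ranking itself excluded a background above 10, so that limit could not test them. A lower limit was not tried, so extra copies of the sequence were not decided for the 20 peaks as a set. Foreign DNA present in the ChIP library alone was not tested and may still account for them, as may strong ZEB1 sites.

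The scarcity of gene-end summits on the X chromosome may come from a single active copy per cell, which would lower pileups below the threshold. At the autosomal rate 67.7 X-linked genes would have had a summit. Keeping each fragment of the autosomal gene-end summits with a chance of 0.5 and asking for at least 8 fragments left 15.6, against 2 observed (one-sided exact Poisson p = 2.38e-05). This estimate takes X-linked promoters to have the pileups of autosomal ones, which the peak list cannot show, so lower dosage as the whole cause and a further loss on the X chromosome cannot be told apart. Away from gene ends the X chromosome had 0.275 peaks per Mb against 0.360 on autosomes (two-sided exact binomial p = 0.0726). That test counted peaks as independent, but some of the 47 on X lay close together. Mid1, a gene outside the naming rule, was assigned 5 of them, with summits from 169986948 to 170019070. Whether peaks were also scarcer on X away from gene ends therefore stays open. The sex of the embryos was not used here.

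The 44 peaks with a fold enrichment under 3 had a median pileup of 79 fragments and a lowest of 15, and 37 of them had a local background above 10 fragments. Their selection favours this, since a lower ratio needs a higher pileup to pass the q limit. The 44 peaks fell into 26 windows of 100 kb, against 43.8 for as many peaks drawn at random from the list (one-sided permutation p = 0.0001, the smallest the draws can give). The highest pileup, 61437 fragments, was on chromosome 2 between 98662300 and 98667231, where fold enrichment was only 1.45 to 1.58.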
